A study of Mus musculus with 36 samples.

How the data were processed

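RNA was measured by sequencing in mouse embryonic fibroblasts of 3 genotypes, wild type (WT), deleted for the kinase GCN2, and deleted for the kinase PERK. Each genotype was left untreated, given the solvent DMSO, starved in medium lacking lysine and arginine (AAS), or given 200 nM thapsigargin, which blocks the calcium pump of the endoplasmic reticulum (ER). Treatment lasted 6 h per the labels. Each of the 12 groups held 3 libraries that the labels call technical replicates, 36 libraries in all. The labels name no more than 1 line per genotype, so genotype and cell line cannot be separated, and every p-value measures only the spread between technical replicates of 1 line. The labels name no control for either stress, nor for the change of medium, so starvation effects may include it.

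The submitters' processing notes name FastQC for read quality, kallisto for quantification and mm10 as the reference, without versions. The deposited table gives TPM (length-normalized transcript abundance with a fixed total per library) per gene symbol, as the authors computed them, for 54735 symbols and 36 libraries. Column totals ran from 999999.83 to 1000000.09, there were 0 duplicate symbols, and 0 per-sample columns were left unused. TPM keeps no record of read depth, so no counting interval and no detection floor could be given. Of the symbols, 54106 matched the GENCODE M21 annotation of GRCm38, which gave gene classes and the loci of the 4 eIF2alpha kinases.

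TPM values were used as deposited, on the scale log2(TPM + 1). Genes with at least 1 TPM in at least 3 libraries were tested: 16083 genes, 12201 of them protein coding and 627 annotated as microRNAs. A linear model over all 12 groups was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow expression level (24 residual degrees of freedom, median prior degrees of freedom 2.33). Every adjusted p is from limma with Benjamini-Hochberg adjustment over all genes tested in that comparison. A gene is said to have risen or fallen when its adjusted p was under 0.05, and counts of 2-fold changes also ask for a log2 change of at least 1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

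There were 16 comparisons: starvation against untreated, thapsigargin against DMSO and DMSO against untreated in each genotype; the difference of each stress effect between each deletion line and WT; the difference between both stress effects in WT; and each deletion line against WT, untreated. A gene was classed as GCN2-dependent when it rose 2-fold with starvation in WT and its response was lower in the GCN2-deletion line. It was also classed as GCN2-selective when it rose with starvation in the PERK-deletion line and responded higher to starvation than to thapsigargin in WT. The PERK-dependent and PERK-selective classes were built in the same way from thapsigargin, with the GCN2-deletion line in the place of the PERK-deletion line. Comparisons in a class share WT libraries. Simulated unchanged groups gave 0 in every class, which says little, since hardly any unchanged gene rises 2-fold. Added after the data were seen were 20 simulations that kept the WT effects and moved the line differences to other genes of like spread. The groups were too small to divide the shared controls between comparisons.

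For 29 lists of genes (stress pathways, metabolism, cell cycle, ribosome, and markers of cell types), members that rose, fell or did not pass were counted, also with adjustment over the list alone. Lists were tested against all other genes with camera in limma at the preset correlation of 0.01, and again with an estimated correlation; these p-values are adjusted over the lists.

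The genes named were set by rule: the 4 eIF2alpha kinases in every group; a panel of 12 stress genes in each treatment comparison; in each comparison the 6 that rose most and the 6 that fell most, with a mean of at least 5 TPM in a compared group and, except for differences of effects, no overlap between the replicates compared; up to 2 that rose most and 2 that fell most in each described list; and the 10 class members with the largest difference of effects and at least 5 TPM in the treated WT group. Gene models without a conventional symbol could be skipped. Groups, comparisons, lists, the naming rule and the settings to be compared were fixed before the data were examined.

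Results were recomputed with the other control for each stress; median-of-ratios rescaling; quantile normalization; leaving out each library in turn; variances without trend; array weights with limma's default method; no filter; a filter at 5 TPM; fitting the compared groups alone; replicate number as a block; a pseudocount of 0.1; DMSO groups in place of untreated ones for the line comparisons; and the estimated correlation for lists. Added after the data were seen were protein-coding genes only, the data without 6 libraries of high microRNA share, and array weights estimated gene by gene. Counts of 2-fold changes were compared with counts from other splits of the same libraries.

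The method was tested on simulated data drawn from a normal distribution around each gene's mean with its fitted residual spread, with known changes added in 1 group to 66, 67 and 67 genes at log2 sizes of 0.5, 1 and 2. For a comparison of 2 groups, 62.1, 91 and 97% of them were recovered, and 13 of 180 calls were false (7.22%). For a difference of effects, 36.4, 83.6 and 95.5% were recovered, and 8 of 152 calls were false (5.26%). Values of some single genes are not reported here.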

Results

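The design sets fibroblasts lacking GCN2 or PERK beside wild-type cells under amino acid starvation and ER stress, to find genes that answer to 1 eIF2alpha kinase and not the other. Eif2ak4 encodes GCN2, the kinase activated by uncharged tRNA, and Eif2ak3 encodes PERK, the kinase of the ER membrane. In the GCN2-deletion line Eif2ak4 mRNA was low but present in every group. In the PERK-deletion line Eif2ak3 mRNA was lowered less and still rose with thapsigargin. The labels do not say which part of either gene was removed, so the TPM of a whole gene may hold transcript that is left after a deletion.

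Eif2ak4, on chromosome 2 from 118388618 to 118475234, stood at 24.6 ± 3.81 TPM (mean ± SD, n = 3 libraries here and in every group) in untreated WT cells. The other WT means were 21.8 ± 1.48 with DMSO, 22.1 ± 0.68 with starvation and 19.6 ± 1.36 with thapsigargin. In the GCN2-deletion line Eif2ak4 stood at 5.25 ± 0.619, 5.87 ± 1.63, 5.62 ± 0.247 and 6.70 ± 1.27 TPM in the same order, and in the PERK-deletion line at 22.7 ± 3.29, 23.2 ± 1.78, 23.4 ± 0.879 and 22.8 ± 0.871 TPM. Untreated, the GCN2-deletion line was lower than WT by a log2 change of -2.03 (SE 0.131, adjusted p = 3.02e-13), and the PERK-deletion line did not differ (-0.11, adjusted p = 0.53). Eif2ak3, on chromosome 6 from 70844515 to 70905245, stood in WT at 6.99 ± 0.878 untreated, 7.29 ± 0.484 with DMSO, 3.98 ± 0.2 with starvation and 11.7 ± 1.17 TPM with thapsigargin. In the GCN2-deletion line it stood at 10.2 ± 1.18, 9.95 ± 0.852, 6.13 ± 0.523 and 19.2 ± 1.92 TPM, and in the PERK-deletion line at 4.22 ± 0.353, 4.50 ± 0.28, 3.77 ± 0.429 and 8.61 ± 0.606 TPM. Untreated Eif2ak3 was lower in the PERK-deletion line than in WT (log2 -0.61, SE 0.097, adjusted p = 6.64e-06) and higher in the GCN2-deletion line (0.48, adjusted p = 0.000175; 0.0535 with the compared groups fitted alone).

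The kinases that answer to other stresses were present in all lines. Eif2ak1, which encodes HRI, stood at 30.9 ± 1.53 TPM in untreated WT, 25.5 in the GCN2-deletion and 24.7 ± 2.4 in the PERK-deletion line. It was lower in both deletion lines (log2 -0.27, adjusted p = 0.000189; -0.31, adjusted p = 2.06e-05) and passed in none of the treatment comparisons. Eif2ak2, which encodes PKR, stood at 32.9 ± 8.64, 15.1 ± 1.85 and 27.1 TPM in the same groups (GCN2-deletion minus WT -1.05, adjusted p = 2.71e-07; PERK-deletion minus WT -0.25, adjusted p = 0.131). Eif2ak2 fell in WT with starvation (-0.47, adjusted p = 0.00901) and with thapsigargin (-0.49, adjusted p = 0.00699). The first call ended without untreated WT replicate 1 (-0.29, adjusted p = 0.12), and the second without WT DMSO replicate 1 or WT thapsigargin replicate 3 (adjusted p up to 0.0539). Eif2ak3 fell with starvation in WT (-0.68, SE 0.097, adjusted p = 3.77e-06) and in the GCN2-deletion line (-0.64, adjusted p = 1.52e-05), but did not pass in the PERK-deletion line (-0.13, adjusted p = 0.462). With thapsigargin it rose in all 3 lines: 0.62 in WT (adjusted p = 1.7e-05), 0.88 in the GCN2-deletion line (3.62e-08) and 0.80 in the PERK-deletion line (1.13e-06).

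**Figure D1:**
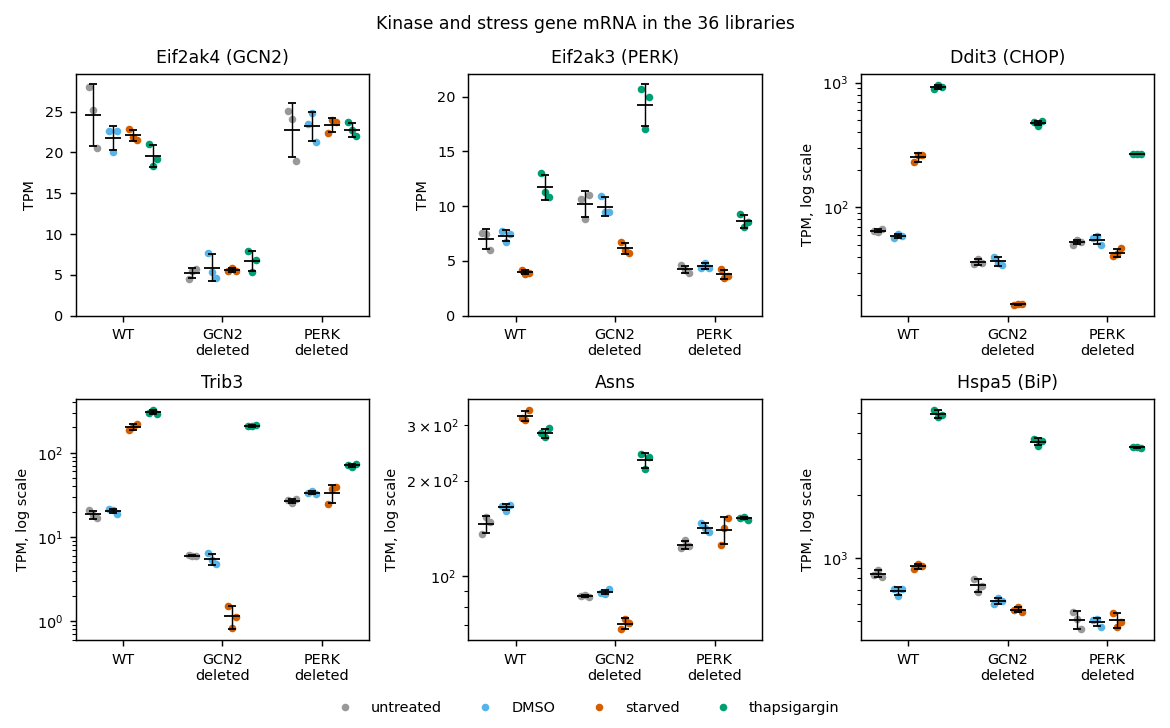
TPM of Eif2ak4, Eif2ak3, Ddit3, Trib3, Asns and Hspa5 (y axis; the last 4 on log axes) by line and treatment (x axis); points are libraries, bars are mean ± SD of 3 libraries. Eif2ak4 stood at 5.25 TPM in the untreated GCN2-deletion line against 24.6 TPM in WT, and Trib3 rose to 203.7 TPM in starved WT cells but stood at 1.15 TPM in the starved GCN2-deletion line.

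Correlations between replicates ran from 0.9621 to 0.9876 over all genes tested. Untreated WT, the control of starvation in WT, varied most (median SD 0.195). Its replicate 1 stood at 65.0 on component 4 against 12.995 and -8.10 for the others, with 9.49% mitochondrial TPM against 7.26 and 7.54%. Without it 406 genes changed 2-fold with starvation in WT, against 428. The share of TPM in genes annotated as microRNAs ran from 0.803 to 3.57%; 6 libraries exceeded 2%, no more than 1 in any group. Mitochondrial transcripts took 4.27 to 9.49% of TPM. The largest components of variance, 30.2 and 25%, separated WT from both deletion lines and the deletion lines from each other. Of the 192 gene places that the rule for the largest changes filled, 42 were held by short transcripts (microRNAs, snoRNAs, snRNAs, 5S rRNA, mitochondrial tRNA), and 28 of these calls ended when 1 library was left out. So did 28 of the other 150, 27 of them effects of DMSO.

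Starvation of WT cells raised the stress genes under the transcription factors ATF4 and CHOP as a group. Trib3, a pseudokinase gene induced by stress, Asns, which makes asparagine, and Fgf21, which encodes a secreted hormone, all rose. Genes that make amino acids and load tRNAs rose with them. Every sterol synthesis gene measured fell, as did genes of mitosis. The ER chaperone gene Hspa5 passed against DMSO but not against untreated cells.

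In WT, starvation raised 2016 and lowered 2794 genes (2633 and 2650 after rescaling), 240 and 188 by 2-fold. Gadd45a, a growth arrest gene, rose most (log2 3.54, SE 0.099, adjusted p = 6.81e-20; 12.01 ± 0.356 to 150.4 ± 16 TPM). Next were Trib3 (3.39, SE 0.122, adjusted p = 5.62e-18), Mir7663 (3.24, adjusted p = 0.039), Fgf21 (3.10), Ciart (3.03) and the peptide hormone gene Adm2 (2.99). The Mir7663 call ended without any of 5 of the 6 libraries (adjusted p up to 0.144). Of the panel, Ddit3, which encodes CHOP, rose by 1.93 (SE 0.062, adjusted p = 7.15e-19), Asns by 1.13 (adjusted p = 2.4e-15), Atf4 by 0.95 (adjusted p = 6.3e-15), Atf3 by 2.83, Chac1 by 2.69, Ppp1r15a by 2.54, Sesn2 by 2.18, Dnajb9 by 0.83 and Psat1 by 0.46. Xbp1 rose by 0.28 (adjusted p = 0.00781; 0.164 with array weights; 0.85 against DMSO), and Hspa5 did not pass (0.12, adjusted p = 0.167; 0.40 and 1.37e-05 against DMSO). Insig1, which restrains sterol synthesis, fell most save the gene model Gm22935 (-4.49; Insig1 -2.84, SE 0.068, adjusted p = 2.49e-21; 85.1 ± 4.45 to 11.02 ± 0.897 TPM). Then came the sterol enzyme genes Hmgcs1 (-2.77), Idi1 (-2.38) and Mvd (-2.37), Mir6965 (-2.74, adjusted p = 0.0287; the call ended without any of 4 of the 6 libraries) and the matrix protease gene Adamts5 (-2.36).

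By list, 24 of 25 ATF4 and CHOP stress genes rose with starvation in WT and 0 fell (24 and 0 adjusted over the list alone, median log2 1.68, camera adjusted p = 3.34e-42, 2.4e-05 with an estimated correlation). All 15 amino acid synthesis and one-carbon genes rose, among them Cth (2.55) and Gpt2 (1.77, median 1.10, adjusted p = 2.26e-25, 0.00288 with an estimated correlation). Of 20 tRNA synthetase genes, 15 rose and 1 fell (Gars 1.10, Wars 1.05, Qars -0.28, lost without either of 2 libraries, median 0.60, adjusted p = 8.55e-14, 0.0385 with an estimated correlation). Amino acid transporters rose in 10 of 15 (11 up and 1 down adjusted over the list alone, Slc7a11 2.93, Slc6a9 2.51), but the list call was lost (adjusted p = 2.92e-10, 0.0745 with an estimated correlation). All 24 sterol genes fell (median -1.35, adjusted p = 2.42e-39, 2.4e-05 with an estimated correlation). Of 23 G2/M genes 22 fell, 23 adjusted over the list alone (Mki67 -1.06, Plk1 -1.003, adjusted p = 7.82e-16, 0.0145 with an estimated correlation). Immediate early genes rose in 17 of 21 (18 up and 1 down adjusted over the list alone, Myc 2.09, Egr2 1.91, adjusted p = 2.48e-17, 0.0109 with an estimated correlation).

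Other lists moved with starvation in WT at the preset correlation alone. Ribosome biogenesis genes rose in 23 of 30 (24 up and 1 down adjusted over the list alone, Nop14 0.86, Wdr43 0.67, adjusted p = 3.5e-11, 0.0566 with an estimated correlation). NF-kappaB and cytokine genes rose in 11 and fell in 2 of 16 (Ptgs2 2.41, Lif 1.78, Cxcl5 -0.90, adjusted p = 5.41e-05, 0.214 with an estimated correlation). NRF2 antioxidant genes rose in 6 and fell in 2 of 19 (Hmox1 1.13, Txnrd1 0.95, adjusted p = 0.00246, 0.223 with an estimated correlation). Heat shock genes fell in 11 and rose in 2 of 21 (2 up and 12 down adjusted over the list alone, Hspa1b -1.97, Hspa8 -1.13, adjusted p = 4.1e-05, 0.194 with an estimated correlation). Interferon-stimulated genes fell in 10 and rose in 1 of 18 (11 and 1 adjusted over the list alone, Stat2 -1.87, Cxcl10 0.97, adjusted p = 0.00359, 0.23 with an estimated correlation). ER chaperones fell in 10 and rose in 1 of 20 (Herpud1 1.97, Sdf2l1 -0.79, Creld2 -0.64, adjusted p = 0.0242, 0.465 with an estimated correlation). Lists that did not pass were hypoxia and glycolysis (7 up, 4 down of 23, adjusted p = 0.0997, median -0.05 against a mean of 0.19, Vegfa 1.80, Ddit4 1.68), p53 targets (9 up, 6 down of 20, adjusted p = 0.238), collagens and matrix (10 up, 7 down of 26, adjusted p = 0.196) and lysosome and autophagy (4 up, 10 down of 26, adjusted p = 0.541). DNA replication (5 up, 5 down of 26, adjusted p = 0.541), IRE1-XBP1 genes (3 up, 4 down of 27, adjusted p = 0.973), mitochondrially encoded genes (0 of 13 passed, adjusted p = 0.829) and ribosomal proteins (0 of 75 passed, adjusted p = 0.0717) did not pass either. Nor did any of 8 lists of cell type markers (adjusted p from 0.13 for fibroblasts to 0.986 for endothelium).

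**Figure D2:**
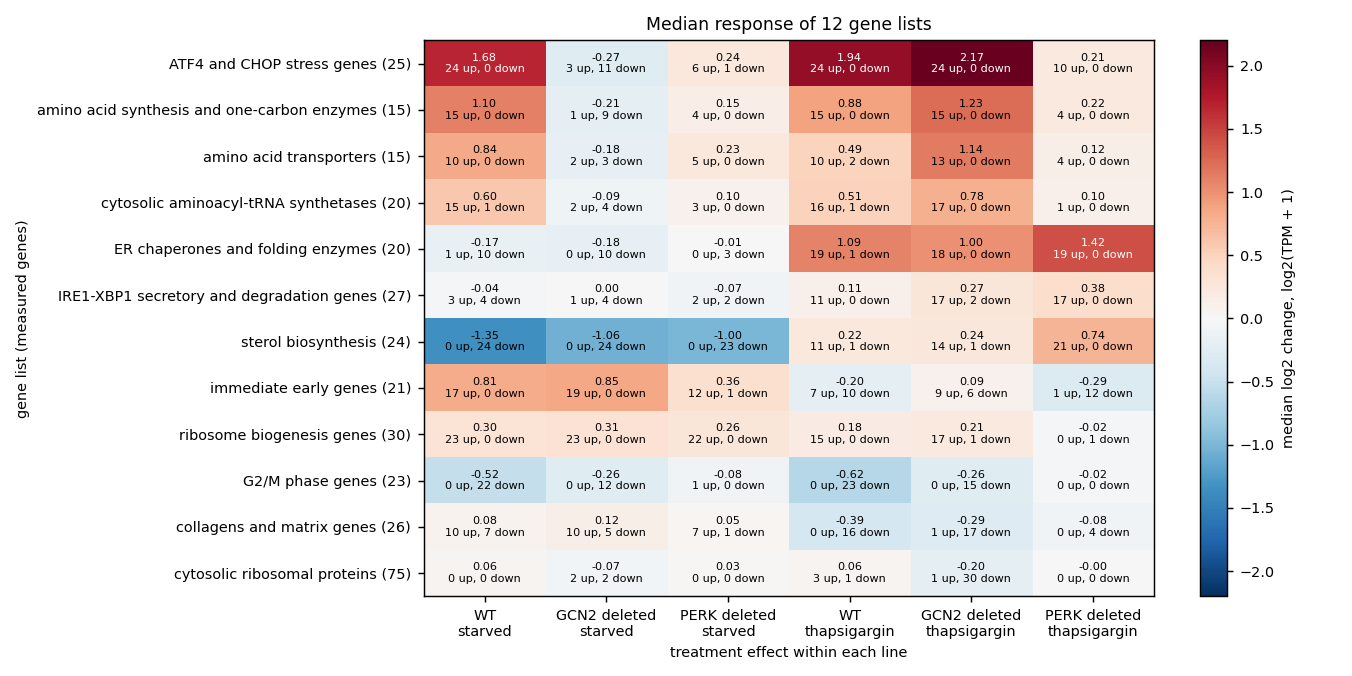
Median log2 change (colour and upper figure) and numbers of genes up and down (lower figure) for 12 lists (y axis) in 6 treatment effects (x axis). The ATF4 and CHOP list had a median of 1.68 in starved WT cells, -0.27 in the starved GCN2-deletion line and 0.24 in the starved PERK-deletion line, while sterol genes had medians of -1.35, -1.06 and -1.001.

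In the GCN2-deletion line, few ATF4 and CHOP genes rose with starvation. Ddit3, Trib3, Chac1, which degrades glutathione, and Sesn2, a stress gene, all ended below their untreated levels. Sterol genes fell and immediate early genes rose, with the cytokine gene Lif and the semaphorin gene Sema7a among the largest rises.

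Starvation raised 1887 and lowered 1956 genes in the GCN2-deletion line (2323 and 2234 after rescaling), 125 and 70 of them at least 2-fold. Trib3 fell by 1.72 (SE 0.122, adjusted p = 2.88e-11), from 6.01 ± 0.119 to 1.15 ± 0.355 TPM, and Ddit3 by 1.08 (SE 0.062, adjusted p = 4.84e-13), from 36.5 ± 1.99 to 16.7 ± 0.0895 TPM. Sesn2 fell by 1.14, Xbp1 by 0.80 (-0.26 against DMSO), Asns by 0.29 and Hspa5 by 0.39 (adjusted p = 3.75e-05), the last not against DMSO (-0.14, adjusted p = 0.128). Atf3 rose (0.86, adjusted p = 6.2e-05), Psat1 fell by 0.16 (adjusted p = 0.0266, lost without any of 5 of the 6 libraries), and Atf4 (-0.04, adjusted p = 0.669), Ppp1r15a (-0.01, 0.998) and Dnajb9 (-0.17, 0.241) did not pass. Sema7a rose most (2.71, SE 0.123, adjusted p = 4.24e-15), then Lif (2.59), Odaph (2.48), the snoRNA Snord59a (2.45, adjusted p = 0.0193), the growth factor gene Areg (2.29) and Wnt11 (2.18). The Snord59a call ended without starved replicate 2 or untreated replicate 1. The largest falls were the microRNA genes Mir6993 (-3.94, adjusted p = 0.0115; 0.257 against DMSO) and Mir6920 (-2.72, adjusted p = 0.0273, lost without any of 4 of the 6 libraries), Hmgcs1 (-2.39), Insig1 (-2.28), Mvd (-2.10) and Chac1 (-1.73).

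All 24 sterol genes fell in the starved GCN2-deletion line (adjusted p = 4.27e-44, 1.83e-05 with an estimated correlation). Of 21 immediate early genes 19 rose (20 adjusted over the list alone, Egr2 2.04, Fosb 1.89, adjusted p = 1.07e-24, 0.00329 with an estimated correlation). Of the 25 ATF4 and CHOP genes 3 rose and 11 fell (3 and 12 adjusted over the list alone, adjusted p = 1.11e-05, 0.158 with an estimated correlation). Of 15 synthesis genes 1 rose and 9 fell (1 up and 10 down adjusted over the list alone, Gpt2 -1.16, Pck2 -1.03, adjusted p = 0.000622, 0.367 with an estimated correlation). Ribosome biogenesis (23 up, 0 down of 30, 25 up and 1 down adjusted over the list alone, adjusted p = 1.12e-11, 0.0771 with an estimated correlation) and NF-kappaB and cytokine genes (12 up, 0 down of 16, adjusted p = 4.41e-11, 0.0595 with an estimated correlation) lost the list call. So did G2/M genes (0 up, 12 down of 23, 14 down adjusted over the list alone, adjusted p = 5.27e-08, 0.156 with an estimated correlation) and ER chaperones (0 up, 10 down of 20, 1 up and 11 down adjusted over the list alone, adjusted p = 7.13e-06, 0.156 with an estimated correlation).

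The starvation response itself was lower in the GCN2-deletion line than in WT for all 25 ATF4 and CHOP genes and all 15 synthesis genes. Gadd45a, Chac1, Adm2 and the glycine transporter gene Slc6a9 lost their responses with Trib3. A response is called higher or lower by the sign of the difference in log2 change, so a gene that fell less responded higher. For the test of the difference, 593 genes had higher and 670 lower responses, 57 and 188 of them by at least 2-fold. The difference was -5.11 for Trib3 (SE 0.172, adjusted p = 7.29e-18), -4.41 for Chac1, -4.10 for Gadd45a (adjusted p = 7.29e-18), -3.41 for Adm2, -3.36 for Slc6a9 and -3.36 for Ciart. Sesn2 (-3.32), the cystine transporter gene Slc7a11 (-3.28), Fgf21 (-3.198) and Herpud1 (-3.18) followed. In the panel it was -3.01 for Ddit3 (adjusted p = 4.13e-19), -2.55 for Ppp1r15a, -1.97 for Atf3, -1.42 for Asns, -1.07 for Xbp1, -1.01 for Dnajb9, -0.98 for Atf4, -0.61 for Psat1 and -0.51 for Hspa5. Higher responses were those of Mir8111 (3.81, adjusted p = 0.0297, lost without any of 6 of the 12 libraries and -0.03 against DMSO), Odaph (2.25), Il11 (1.81), Gjb2 (1.76; 0.54 and adjusted p = 0.352 with a pseudocount of 0.1), Bmp4 (1.63) and Ell2 (1.54). Eif2ak2 differed by 0.71 (adjusted p = 0.0168), but by 0.10 against DMSO (adjusted p = 0.865), and 3 of the 12 libraries each ended the call when left out.

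By list, the difference between the GCN2-deletion line and WT held with an estimated correlation for ATF4 and CHOP genes (0 higher, 25 lower, median -1.97, adjusted p = 7.44e-82, 8.97e-08 with an estimated correlation). So it did for synthesis genes (0 and 15, Gpt2 -2.94, Cth -2.77, adjusted p = 5.36e-48, 6.79e-05 with an estimated correlation), tRNA synthetases (0 and 14 of 20, 15 lower adjusted over the list alone, Cars -1.42, Gars -1.22, adjusted p = 1.38e-24, 0.00579 with an estimated correlation) and amino acid transporters (0 and 9 of 15, 10 lower adjusted over the list alone, adjusted p = 1.67e-16, 0.0255 with an estimated correlation). Sterol genes (8 higher of 24, 11 adjusted over the list alone, Hsd17b7 1.34, Idi1 1.03, adjusted p = 1.14e-06, 0.131 with an estimated correlation), G2/M genes (8 higher of 23, 13 adjusted over the list alone, adjusted p = 6.96e-07, 0.17 with an estimated correlation) and NRF2 genes (4 lower of 19, 5 lower adjusted over the list alone, Hmox1 -1.49, adjusted p = 0.000256, 0.17 with an estimated correlation) lost the call. Of the 240 genes that rose at least 2-fold in WT, 178 were GCN2-dependent, 164 of them protein coding. Independent sets would share 10. Simulations (20) with line differences moved to other genes and WT libraries shared gave 28.3 on average (at most 39, own independent value 21.6). Part of the excess may come from sharing.

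The PERK-deletion line also answered starvation with little of the ATF4 program. Atf4, Atf3, Trib3, Chac1 and Sesn2 did not pass, and neither did Asns, but without starved replicate 1 Trib3, Chac1 and Asns rose. Sterol genes fell and ribosome biogenesis genes rose in this line.

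Starvation raised 924 and lowered 1027 genes in the PERK-deletion line (1300 and 1165 after rescaling), 62 and 52 at least 2-fold. Trib3 stood at 27.1 ± 1.49 TPM untreated and 33.6 ± 7.98 starved (log2 0.27, SE 0.122, adjusted p = 0.157), and Asns at 125.6 ± 3.8 and 139.6 ± 13.6 (0.15, adjusted p = 0.0745). Atf4 (0.02, adjusted p = 0.881), Atf3 (-0.11, 0.735), Chac1 (0.05, 0.879), Sesn2 (0.00, 1), Ppp1r15a (-0.03, 0.933), Hspa5 (-0.01, 0.972) and Dnajb9 (-0.19, 0.269) did not pass. Starved replicate 1 stood apart, with 3.47% of TPM in microRNA genes; without it Trib3 (0.48, adjusted p = 0.00265), Chac1 (0.28, 0.0158) and Asns (0.22, 0.00409) rose. Ddit3 fell by 0.27 (adjusted p = 0.00338; 0.139 with the compared groups fitted alone), Xbp1 by 0.35 (adjusted p = 0.0028; 0.892 against DMSO), and Psat1 rose by 0.19 (adjusted p = 0.0151, lost without starved or untreated replicate 3). The largest rises were Mir6984 (3.08, adjusted p = 0.00262), Mir6407 (2.94, adjusted p = 0.287 against DMSO), Mir130b (2.64), Sema7a (2.07, SE 0.123, adjusted p = 1.59e-12), Snord88c (1.98, lost without any of 3 of the 6 libraries) and the serine protease gene Prss22 (1.56). The largest falls were the snRNA Rnu5g (-3.65, adjusted p = 0.00581; 0.0694 with the compared groups fitted alone), Mir1954 (-3.24, lost without untreated replicate 3), the 5S rRNA n-R5s204 (-2.87, lost without either of 2 libraries), Mir674 (-2.60, lost without any of the 6), Hmgcs1 (-1.92, adjusted p = 1.7e-15) and Atoh8 (-1.73).

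Sterol genes fell in 23 of 24 in the starved PERK-deletion line (Insig1 -1.70, median -1.001, adjusted p = 1.61e-53, 3.64e-06 with an estimated correlation). Ribosome biogenesis genes rose in 22 of 30 (26 adjusted over the list alone, Polr1b 0.54, Dkc1 0.45, adjusted p = 2.56e-17, 0.0326 with an estimated correlation). ATF4 and CHOP genes rose in 6 and fell in 1 of 25 (8 and 1 adjusted over the list alone, Ndrg1 1.20, adjusted p = 0.000146, 0.356 with an estimated correlation). Transporters rose in 5 of 15 (5 up and 1 down adjusted over the list alone, Slc7a11 1.38, adjusted p = 0.00189, 0.523 with an estimated correlation) and synthesis genes in 4 of 15 (9 up and 1 down adjusted over the list alone, adjusted p = 0.000902, 0.523 with an estimated correlation). Immediate early genes rose in 12 and fell in 1 of 21 (14 and 2 adjusted over the list alone, Fosb 1.52, Egr3 1.17, Dusp1 -0.38, adjusted p = 7.13e-12, 0.0671 with an estimated correlation). Mitochondrially encoded genes fell in 4 of 13, 9 adjusted over the list alone (adjusted p = 0.000298, 0.523 with an estimated correlation); starved replicate 1 held 4.33% mitochondrial TPM against 7.795 and 7.97% in its replicates.

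Against WT, the starvation response of the PERK-deletion line was higher for 898 and lower for 859 genes (1056 and 1233 after rescaling), 88 and 183 by at least 2-fold. It was lower for Gadd45a (-3.64, SE 0.14, adjusted p = 4.48e-16), Trib3 (-3.12, adjusted p = 5.05e-13), Ciart (-2.98), Atf3 (-2.93), Chac1 (-2.64), Ppp1r15a (-2.58), Ddit3 (-2.21), Sesn2 (-2.18), Dnajb9 (-1.02), Asns (-0.98), Atf4 (-0.93), Xbp1 (-0.63) and Psat1 (-0.27, adjusted p = 0.015; 0.0551 without untreated PERK-deletion replicate 2). Hspa5 did not pass (-0.13, adjusted p = 0.428; -0.38 and 0.00485 against DMSO). Eif2ak3 differed by 0.55 (adjusted p = 0.00849; 0.0912 with the compared groups fitted alone). Short RNAs with lower responses were Rnu5g (-6.43), Mir674 (-3.96, lost without starved WT replicate 3) and Rn7sk (-3.13, lost without any of 7 of the 12 libraries). Higher responses were those of Mir6984 (3.76), Mir6407 (3.66, lost without either of 2 libraries), Mir130b (2.64, lost without any of 11 of the 12), S100a7a (2.63, adjusted p = 0.136 against DMSO), the peptide hormone gene Ucn2 (2.36, adjusted p = 0.0928 against DMSO) and Rasl11a (2.15, adjusted p = 2.22e-09).

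ATF4 and CHOP genes had lower starvation responses than in WT in 22 of 25 (23 adjusted over the list alone, median -1.41, adjusted p = 3.66e-50, 7.31e-06 with an estimated correlation). Responses were lower for synthesis genes in 15 of 15 (Cth -2.26, Psph -1.92, adjusted p = 8.18e-29, 0.00202 with an estimated correlation) and tRNA synthetases in 14 of 20 (1 higher and 15 lower adjusted over the list alone, adjusted p = 5.49e-14, 0.0419 with an estimated correlation). G2/M genes had higher responses in 17 of 23 (20 adjusted over the list alone, Mki67 0.95, Plk1 0.94, adjusted p = 2.72e-17, 0.0115 with an estimated correlation). Sterol genes fell less than in WT in 14 of 24 (21 adjusted over the list alone, Insig1 1.14, Mvd 1.05, adjusted p = 8.11e-14, 0.0115 with an estimated correlation). Transporters (9 lower of 15, 1 higher and 10 lower adjusted over the list alone, adjusted p = 1.73e-09, 0.103 with an estimated correlation), immediate early genes (11 lower and 1 higher of 21, 1 higher and 14 lower adjusted over the list alone, Egr2 -1.12, Klf4 -1.06, adjusted p = 1.96e-09, 0.0825 with an estimated correlation) and heat shock genes (8 higher, 1 lower of 21, 9 higher and 1 lower adjusted over the list alone, Hspa1b 1.44, Hspa8 0.82, adjusted p = 2.48e-05, 0.193 with an estimated correlation) lost the call. Of the 178 GCN2-dependent genes, 168 also had a lower response in the PERK-deletion line (9.51 for independent sets, at most 36 in simulations with shared WT libraries). So had 205 of the 240 that rose 2-fold in WT (12.8, at most 55). Part of both may come from that sharing. Among the 240, 82 rose in the starved PERK-deletion line.

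Thapsigargin in WT raised the ATF4 program and the ER chaperones together. Herpud1, which serves protein removal from the ER, rose most, with Gadd45a, Ddit3 and Trib3 close behind. Hspa5, the main ER chaperone gene, and Xbp1, a transcription factor gene of the ER stress response, rose too. Genes of mitosis fell.

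In WT, thapsigargin raised 1838 and lowered 2384 genes (2451 and 2379 after rescaling), 221 and 149 at least 2-fold. Herpud1 rose by 4.32 (SE 0.094, adjusted p = 8.69e-23; 44.2 ± 2.05 to 901.4 ± 15.7 TPM), Gadd45a by 4.01 (adjusted p = 1.08e-21), Ddit3 by 3.94 (adjusted p = 4.6e-26; 58.9 ± 1.81 to 920.7 ± 36.3 TPM), Trib3 by 3.83, Ciart by 3.81 and Fgf21 by 3.70. Other panel genes were Atf3 (3.63), Ppp1r15a (3.54), Chac1 (3.44), Hspa5 (2.83, SE 0.063, adjusted p = 9.49e-23), Dnajb9 (2.69), Xbp1 (2.60), Sesn2 (2.19), Atf4 (1.33, adjusted p = 3.46e-18), Asns (0.77) and Psat1 (0.19, adjusted p = 0.00739). The largest falls were Mir7013 (-2.70, adjusted p = 0.0243, lost without any of 4 of the 6 libraries), Mir5623 (-2.57, adjusted p = 0.1 against untreated cells), n-R5s204 (-2.39, lost without any of 3 of the 6), the helicase gene Pif1 (-2.01, adjusted p = 2.23e-10), Oaf (-1.92) and Irs1 (-1.83), an adaptor of the insulin receptor.

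ATF4 and CHOP genes rose with thapsigargin in 24 of 25 (median 1.94, adjusted p = 3.87e-48, 1.03e-05 with an estimated correlation). ER chaperones rose in 19 of 20 and fell in 1 (Sdf2l1 3.13, Hspa13 -0.31, the last call lost without any of 4 libraries, adjusted p = 3.67e-30, 0.000167 with an estimated correlation). Synthesis genes rose in 15 of 15 (Cth 1.89, Gpt2 1.401, adjusted p = 1.8e-20, 0.00682 with an estimated correlation). tRNA synthetases rose in 16 and fell in 1 of 20 (Wars 1.05, Tars 0.90, Qars -0.28, the last lost without any of 4 libraries, adjusted p = 4.39e-14, 0.0419 with an estimated correlation). All 23 G2/M genes fell (Plk1 -1.11, Mki67 -1.06, adjusted p = 3.51e-21, 0.00571 with an estimated correlation).

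Other lists lost the call in WT with thapsigargin. Transporters rose in 10 and fell in 2 of 15 (Slc3a2 1.93, Slc6a9 1.91, Slc38a9 -0.59, adjusted p = 1.84e-07, 0.169 with an estimated correlation). IRE1-XBP1 genes rose in 11 of 27 (adjusted p = 2.8e-07, 0.0868 with an estimated correlation). Sterol genes rose in 11 and fell in 1 of 24 (13 and 1 adjusted over the list alone, Msmo1 0.78, Insig1 0.70, adjusted p = 5.7e-07, 0.0905 with an estimated correlation). Collagens fell in 16 of 26 (18 adjusted over the list alone, Ctgf -1.40, Timp3 -1.21, adjusted p = 5.37e-07, 0.211 with an estimated correlation). Ribosome biogenesis genes rose in 15 of 30 (16 adjusted over the list alone, adjusted p = 5.7e-07, 0.171 with an estimated correlation).

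In the PERK-deletion line thapsigargin still raised the ER chaperones and the XBP1 branch. Sdf2l1 and Manf, genes of ER proteins, rose with Hspa5 and Xbp1. The ATF4 branch rose less, and Asns passed only against untreated cells. Sterol genes rose, and the immediate early gene Egr1 fell.

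Thapsigargin raised 402 and lowered 451 genes in the PERK-deletion line, 54 and 31 at least 2-fold; 47.1% of changed genes rose, and 59.6% after median-of-ratios rescaling. Sdf2l1 rose by 3.09 (SE 0.077, adjusted p = 2.67e-21), Herpud1 by 2.89, Hspa5 by 2.79 (SE 0.063, adjusted p = 4.4e-22; 492.7 ± 21.2 to 3405 ± 32.7 TPM), Mir7231 by 2.74 (adjusted p = 0.0315, lost without any of the 6 libraries), Manf by 2.32 and Xbp1 by 2.30. Ddit3 rose by 2.27 (adjusted p = 2.07e-20; 55.1 ± 4.45 to 268.5 ± 1.59 TPM), Dnajb9 by 2.10, Chac1 by 1.21, Trib3 by 1.07, Atf3 by 0.84, Ppp1r15a by 0.70, Atf4 by 0.57 and Sesn2 by 0.51; Asns (0.10, adjusted p = 0.428) and Psat1 (0.14, 0.151) passed only against untreated cells (0.27 and 0.22). The largest falls were Mir5618 (-2.93, lost without any of 5 of the 6 libraries), Pbxip1 (-2.11, SE 0.088, adjusted p = 2.8e-16), Scara3 (-1.88), Egr1 (-1.88), Angptl2 (-1.73) and P3h4 (-1.70).

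ER chaperones rose in 19 of 20 in the thapsigargin-treated PERK-deletion line (20 adjusted over the list alone, median 1.42, adjusted p = 4.28e-98, 1.24e-08 with an estimated correlation). IRE1-XBP1 genes rose in 17 of 27 (22 adjusted over the list alone, Derl3 2.26, adjusted p = 3.74e-46, 4.7e-06 with an estimated correlation). Sterol genes rose in 21 of 24 (22 adjusted over the list alone, Insig1 1.29, Mvd 1.13, adjusted p = 1.38e-60, 6.43e-07 with an estimated correlation) and ATF4 and CHOP genes in 10 of 25 (13 adjusted over the list alone, adjusted p = 5.7e-22, 0.00083 with an estimated correlation). Synthesis genes (4 up of 15, 8 adjusted over the list alone, adjusted p = 2.09e-08, 0.115 with an estimated correlation) and immediate early genes (1 up, 12 down of 21, 3 up and 12 down adjusted over the list alone, Klf4 0.57, Junb -1.07, adjusted p = 6.19e-08, 0.115 with an estimated correlation) lost the call.

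The test of the difference gave 899 higher and 1187 lower thapsigargin responses in the PERK-deletion line than in WT, 90 and 172 by at least 2-fold. Lower were Fgf21 (-3.58, SE 0.205, adjusted p = 1.3e-12; 0.148 ± 0.142 TPM with thapsigargin against 18.1 ± 1.14 in WT), Gadd45a (-3.43, adjusted p = 1.01e-15), Snord15a (-3.02, lost without any of 9 of the 12 libraries), Ciart (-2.88), Ppp1r15a (-2.84), Atf3 (-2.79), H2-Bl (-2.79), Cox6a2 (-2.77), Trib3 (-2.76) and Acot2 (-2.60). In the panel Chac1 (-2.22), Sesn2 (-1.68), Ddit3 (-1.68, adjusted p = 3.81e-13), Atf4 (-0.77, adjusted p = 2.64e-09), Asns (-0.67) and Dnajb9 (-0.59, adjusted p = 0.00563; 0.106 against untreated cells) were lower too. Hspa5 (-0.05, adjusted p = 0.821), Xbp1 (-0.30, 0.0779) and Psat1 (-0.05, 0.751) did not pass. Higher were Mir7013 (4.49, lost without PERK-deletion DMSO replicate 1), Mir7231 (3.43, lost without any of 9 of the 12 libraries), Mir186 (2.40, lost without any of 6), Cdc42ep2 (1.70, adjusted p = 2.79e-10), Gas1 (1.69) and Irs1 (1.68).

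Of 25 ATF4 and CHOP genes 23 had lower thapsigargin responses in the PERK-deletion line than in WT (median -1.36, adjusted p = 4.76e-46, 1.48e-05 with an estimated correlation). So had 12 of 15 synthesis genes (14 adjusted over the list alone, Cth -1.67, Gpt2 -1.13, adjusted p = 6.09e-15, 0.027 with an estimated correlation). G2/M genes had higher responses in 22 of 23 (23 higher adjusted over the list alone, Cenpf 1.06, Mki67 1.04, adjusted p = 6.16e-24, 0.00428 with an estimated correlation) and sterol genes in 14 of 24 (21 adjusted over the list alone, Hmgcs1 0.88, adjusted p = 1.48e-12, 0.0194 with an estimated correlation). tRNA synthetases (13 lower of 20, 1 higher and 16 lower adjusted over the list alone, adjusted p = 1.49e-10, 0.11 with an estimated correlation), transporters (8 lower of 15, 1 higher and 8 lower adjusted over the list alone, Slc1a4 -1.53, Slc3a2 -1.37, adjusted p = 4.86e-05, 0.27 with an estimated correlation) and ER chaperones (7 higher, 1 lower of 20, 8 higher and 1 lower adjusted over the list alone, Hspa13 0.62, Herpud1 -1.43, adjusted p = 0.00202, 0.27 with an estimated correlation) lost the call. Of the 221 genes that thapsigargin raised at least 2-fold in WT, 187 were PERK-dependent, 164 of them protein coding (16.3 for independent sets, at most 45 in such simulations; part may come from the sharing), and 65 rose in the PERK-deletion line.

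Thapsigargin changed more genes in the GCN2-deletion line than in WT. Trib3, Chac1, Herpud1 and Atf3 rose most, and amino acid synthesis genes rose with the ER chaperones.

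Thapsigargin raised 4093 and lowered 1815 genes in the GCN2-deletion line, 456 and 124 at least 2-fold. The share that rose, 69.3%, was 48.2% after rescaling, which shifted the median of all genes by -0.10. Processed pseudogenes took 5.96 to 7.90% of TPM in its thapsigargin libraries against 3.65 to 3.91% with DMSO. Trib3 rose by 5.03 (SE 0.122, adjusted p = 5.83e-22), Chac1 by 4.73 (SE 0.114, adjusted p = 5.83e-22), Herpud1 by 4.50, Atf3 by 4.30, Gadd45a by 4.19 and Adm2 by 3.67. The panel genes Ddit3 (3.65), Dnajb9 (3.00), Sesn2 (2.88), Ppp1r15a (2.85), Hspa5 (2.54), Xbp1 (2.39), Atf4 (1.54), Asns (1.37) and Psat1 (0.59) rose as well. All of the 6 largest falls were short RNAs: Mir763 (-3.99, adjusted p = 0.000187), the mitochondrial tRNA mt-Tw (-3.60, adjusted p = 0.00138), Mir6960 (-2.88, adjusted p = 0.0597 with the compared groups fitted alone), Mir7664 (-2.82, lost without any of 3 of the 6 libraries), Mir1957a (-2.78, lost without DMSO replicate 1) and n-R5s85 (-2.64).

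ATF4 and CHOP genes rose in 24 of 25 in the thapsigargin-treated GCN2-deletion line (median 2.17, adjusted p = 2.07e-34, 0.000142 with an estimated correlation). Synthesis genes rose in 15 of 15 (Gpt2 2.56, Aldh1l2 2.40, adjusted p = 9.18e-18, 0.0164 with an estimated correlation) and ER chaperones in 18 of 20 (adjusted p = 2.64e-16, 0.00768 with an estimated correlation). The call was lost for transporters (13 up of 15, Slc7a11 3.05, adjusted p = 5.77e-09, 0.123 with an estimated correlation), tRNA synthetases (17 up of 20, 18 up adjusted over the list alone, Aars 1.10, Cars 1.08, adjusted p = 7.74e-11, 0.082 with an estimated correlation) and G2/M genes (15 down of 23, 16 adjusted over the list alone, adjusted p = 2.3e-10, 0.082 with an estimated correlation). The same held for ribosomal proteins (1 up, 30 down of 75, 1 and 32 adjusted over the list alone, Rpl24 -0.78, Rpl37a -0.77, adjusted p = 4.94e-10, 0.345 with an estimated correlation) and mitochondrially encoded genes (4 down of 13, 5 down adjusted over the list alone, adjusted p = 0.000437, 0.338 with an estimated correlation).

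Compared with WT, the thapsigargin response was higher for 1978 and lower for 314 genes in the GCN2-deletion line, 260 and 34 by at least 2-fold. The share of higher responses, 86.3%, was 54% after rescaling, which shifted the median of all genes by -0.15. Responses were higher for Chac1 (1.30, SE 0.162, adjusted p = 4.58e-06), Trib3 (1.20, adjusted p = 3.62e-05), Sesn2 (0.69) and Asns (0.60, adjusted p = 5.27e-06), and lower for Ppp1r15a (-0.69, adjusted p = 0.00973). Psat1 (0.40, adjusted p = 0.000582), Atf3 (0.67, 0.0312) and Atf4 (0.21, 0.0363) passed but not after rescaling (0.112, 0.118 and 0.945). Atf4 was also lost without any of 10 of the 12 libraries (adjusted p up to 0.0997) and Atf3 without any of 8 (0.0835). Ddit3 (-0.29, adjusted p = 0.0274) and Hspa5 (-0.29, 0.0304) did not pass after quantile normalization, where Hspa5 turned to 0.28. Each was also lost without any of 6 of the 12 libraries (adjusted p up to 0.0798 and 0.0729). Dnajb9 (0.32, adjusted p = 0.143) and Xbp1 (-0.21, 0.21) did not pass. The largest values were those of Mir7013 (4.86, adjusted p = 0.0115), Snord15b (3.98) and the 5S rRNA genes n-R5s100, n-R5s103, n-R5s104 and n-R5s105 (each 3.44, lost without any of 6 of the 12 libraries). Lower responses were those of Mir679 (-2.58, lost without any of 11 of the 12 libraries), U90926 (-1.80, adjusted p = 2.09e-08), Adm (-1.56), Car6 (-1.42), H2-Bl (-1.37) and Fgf21 (-1.29). The last 4 did not pass with a pseudocount of 0.1, where Fgf21 turned to 0.34.

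No list difference from WT in the thapsigargin response of the GCN2-deletion line held with an estimated correlation. Responses of ATF4 and CHOP genes were higher in 11 and lower in 6 of 25 (13 and 7 adjusted over the list alone, Vldlr 2.49, Adm2 1.36, Cdsn -1.18, adjusted p = 0.169). Those of synthesis genes were higher in 7 of 15 (8 higher adjusted over the list alone, Aldh1l2 1.17, Gpt2 1.15, adjusted p = 0.000181, 0.346 with an estimated correlation). Those of G2/M genes were higher in 14 of 23 (15 higher adjusted over the list alone, Mki67 0.88, Hmmr 0.67, adjusted p = 4.61e-06, 0.309 with an estimated correlation) and those of ribosomal proteins lower in 6 of 75 (3 lower adjusted over the list alone, adjusted p = 4.79e-20, 0.346 with an estimated correlation). Without WT thapsigargin replicate 1, 2 or 3 the 2-fold count of 294 was 488, 187 or 164. Of the 221 genes raised 2-fold in WT, 204 rose in this line (56.2 for independent sets). Responses were lower than in WT for 52 (4.31 for independent sets, 19.2 on average and at most 28 in simulations with shared WT libraries). They were higher for 33 (27.2, 41.8 and 49). Independent sets in the simulations gave 12.7 and 50, above the 4.31 and 27.2 of the data. The 33 can therefore not be read as more or fewer than the simulations give.

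**Figure D3:**
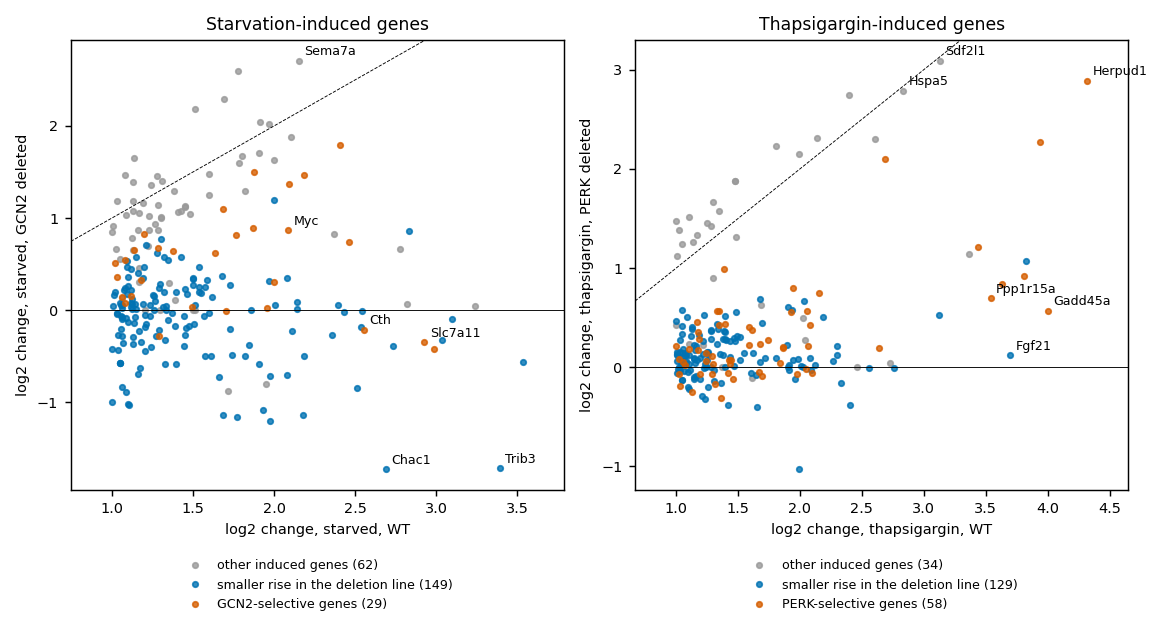
Log2 change in WT (x axis) against that in a deletion line (y axis) for genes that rose at least 2-fold in WT; each point is a gene and the dashed line marks equal change. With starvation (left) 178 of 240 genes had a lower response in the GCN2-deletion line, 29 of them GCN2-selective; with thapsigargin (right) 187 of 221 had a lower response in the PERK-deletion line, 58 of them PERK-selective.

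Set side by side in WT, both stresses raised the ATF4 program, and they parted on chaperones and sterols. Sterol genes fell with starvation, while most of them rose or did not pass with thapsigargin. Hspa5 and Sdf2l1 rose with thapsigargin, while Sdf2l1 fell with starvation.

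Starvation and thapsigargin raised 117 genes in common at least 2-fold (3.3 for independent sets) and lowered 24 (1.74). Responses to starvation were higher than those to thapsigargin for 928 genes and lower for 993 (1436 and 1334 after rescaling), 174 and 143 by at least 2-fold; with the controls exchanged the 2-fold count of 317 was 601. Kansl2-ps led (4.05, adjusted p = 0.0459, lost without any of 9 of the 12 libraries), and high among the others were Dusp6 (3.204, SE 0.15, adjusted p = 3.26e-15), Sema7a (3.00), Ctgf (2.79) and the hyaluronan synthase gene Has2 (2.73). At the other end were Sdf2l1 (-3.91, SE 0.108, adjusted p = 4.63e-20), Insig1 (-3.55), Mvd (-2.97), Hmgcs1 (-2.94), Idi1 (-2.72) and Hspa5 (-2.72). In the panel Xbp1 (-2.33), Ddit3 (-2.01, adjusted p = 8.3e-16), Dnajb9 (-1.85), Ppp1r15a (-0.997), Atf3 (-0.80), Chac1 (-0.75) and Atf4 (-0.38) responded lower to starvation, and Eif2ak3 did so by -1.29 (adjusted p = 7.98e-08). Asns (0.36, adjusted p = 0.00151; -0.002 with the controls exchanged) and Psat1 (0.27, 0.0137; 0.279 with the controls exchanged) responded higher, while Trib3 (-0.44, 0.102; 0.00426 with the controls exchanged) and Sesn2 (-0.01, 0.984) did not pass.

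In WT, sterol genes responded lower to starvation than to thapsigargin in 24 of 24 (adjusted p = 6.59e-66, 5.77e-07 with an estimated correlation) and ER chaperones in 17 of 20 (18 adjusted over the list alone, adjusted p = 2.41e-39, 2.32e-05 with an estimated correlation). Immediate early genes were higher in 15 and lower in 2 of 21 (16 higher and 2 lower adjusted over the list alone, Egr2 2.16, Egr1 2.08, Fosb -0.68, lost without any of 8 of the 12 libraries, Klf4 -0.56, lost without starved replicate 1, adjusted p = 3.67e-18, 0.0113 with an estimated correlation). Fibroblast markers were higher in 3 of 14 (8 adjusted over the list alone, Snai1 0.998, Cd44 0.81, adjusted p = 0.00273, 0.0326 with an estimated correlation), and collagens in 13 of 26 (15 higher and 1 lower adjusted over the list alone, Timp3 1.92, adjusted p = 6.3e-08, 0.19 with an estimated correlation).

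GCN2-selective genes numbered 29, all protein coding (54 after rescaling, 46 with quantile normalization, 52 with array weights gene by gene, 44 without the 6 libraries of high microRNA share), and PERK-selective genes 58, 47 of them protein coding. Of the 178 GCN2-dependent and 187 PERK-dependent genes, 110 were in both classes (2.07 for independent sets). The 10 leading GCN2-selective genes, with log2 changes in starved WT, starved GCN2-deletion and thapsigargin-treated WT cells, were Adm2 (2.99, -0.43, 2.30), Slc7a11 (2.93, -0.35, 1.48), Cth (2.55, -0.21, 1.89), Arid5a (2.46, 0.74, 1.96), Myc (2.09, 0.87, 1.42), Mex3b (2.00, 0.31, 1.23), Etv5 (1.96, 0.02, 0.85), Phf10 (1.70, -0.01, 1.25), Gcnt4 (1.64, 0.62, 0.14) and Eif4ebp1 (1.29, -0.28, 0.93). The class asks for a higher response to starvation, not for none to thapsigargin, nor for independence of PERK: 9 of the 29, and 7 of these 10, were also PERK-dependent. Of the 58 PERK-selective genes 17, and 7 of the 10 below, were also GCN2-dependent. The 10 leading PERK-selective genes, with log2 changes in thapsigargin-treated WT, thapsigargin-treated PERK-deletion and starved WT cells, were Gadd45a (4.01, 0.57, 3.54), Ciart (3.81, 0.92, 3.03), Atf3 (3.63, 0.84, 2.83), Ppp1r15a (3.54, 0.70, 2.54), Chac1 (3.44, 1.21, 2.69), Stard5 (2.64, 0.20, 2.11), Rassf5 (2.06, 0.22, 1.32), Casp4 (2.05, -0.02, 0.66), Snhg12 (1.98, -0.06, 0.44) and Tslp (1.70, -0.09, 0.95).

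DMSO alone moved few genes. Hist1h1c, a linker histone gene, rose in all 3 lines. The call ended without any of 3 of the 6 libraries in WT (adjusted p up to 0.0594) and either of 2 in the GCN2-deletion line (0.0959). In WT 7 genes rose and 12 fell with limma, 0 of them by 2-fold, and 2258 genes had an unadjusted p under 0.05. In the GCN2-deletion line 9 rose and 15 fell (2 by 2-fold; 1275 unadjusted), and in the PERK-deletion line 22 rose and 17 fell (2 by 2-fold; 1413 unadjusted). In WT the largest changes were Hist1h1c (0.66, adjusted p = 0.00978), Sqstm1 (0.38), Nqo1 (0.35, adjusted p = 0.00488), Txnrd3 (0.34), Cyr61 (0.31), Plaur (0.27), Speg (-0.59), Sema3f (-0.58), Xbp1 (-0.57, adjusted p = 0.00154), Podnl1 (-0.45), Sdf2l1 (-0.39) and Tra2a (-0.35). Those of the GCN2-deletion line were Hist1h1c (0.60), Mt2 (0.45), Hmox1 (0.40, adjusted p = 0.00145), Arl2bp (0.28), Plaur (0.27), Metap1 (0.23), Hspa8 (-0.55), Xbp1 (-0.54, adjusted p = 0.000748), Sdf2l1 (-0.53), H19 (-0.48), Rad51c (-0.45) and Nupr1 (-0.45). Those of the PERK-deletion line were Dock3 (0.89), Hist1h1c (0.76, adjusted p = 0.000739), Tmco4 (0.62), Hmox1 (0.47, adjusted p = 0.000334), Ctns (0.47), Pmepa1 (0.47), Thbs2 (-0.59), Cavin2 (-0.54, adjusted p = 0.00186), Adamts1 (-0.46), Ptn (-0.44), Ech1 (-0.39) and Ripk3 (-0.38).

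All of these named DMSO calls ended when the compared groups were fitted alone. Of the 36, 27 also ended when 1 library was left out (11 of 12 in WT, 7 in the GCN2-deletion and 9 in the PERK-deletion line). The share of changed genes that rose with DMSO was 36.8% in WT and 48.3% after rescaling, and 56.4 and 34.6% in the PERK-deletion line. Without untreated WT replicate 3 the WT count of 2-fold changes was 84, and without replicate 2 it was 7. NRF2 genes rose as a list in WT (1 of 19, 8 adjusted over the list alone, camera adjusted p = 1.86e-12, 0.0142 with an estimated correlation). Sterol genes fell as a list in the PERK-deletion line (0 of 24, 11 adjusted over the list alone, adjusted p = 6.55e-12, 0.0296 with an estimated correlation). So did neural (0 of 7, 3 adjusted over the list alone, adjusted p = 2.15e-05, 0.0054 with an estimated correlation) and skeletal muscle markers (0 of 4, 2 adjusted over the list alone, adjusted p = 0.00565, 0.0424 with an estimated correlation). In the GCN2-deletion line ER chaperones lost the list call (2 down of 20, 9 adjusted over the list alone, adjusted p = 3.32e-11, 0.0753 with an estimated correlation).

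The untreated lines differed far more than any treatment moved them. Tagln and Acta2, genes of smooth muscle, were high in both deletion lines. The fibroblast collagens Col1a1 and Col3a1 were far lower in the PERK-deletion line than in WT.

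The GCN2-deletion line had 3413 genes higher and 3732 lower than WT (3933 and 3661 after rescaling), 898 and 669 by 2-fold, and the PERK-deletion line 5022 and 2986, 1065 and 590 by 2-fold; of the last comparison 62.7% were higher, and 50.2% after rescaling. The largest values of the GCN2-deletion line were those of gene copies: Eno1b (9.91, SE 0.136, adjusted p = 1.87e-28), Rpl34-ps1 (9.64), Rpl3-ps1 (9.27), Rpl15-ps2 (7.84), Hmga1b (7.64) and Atp6v0c-ps2 (7.28), with Rpl15-ps3 at -9.44. Lower too were Shox2 (-5.17), Platr16 (-5.02), Ahcy (-4.55, SE 0.079, adjusted p = 2.86e-26; 243.7 ± 29.6 TPM in WT, 9.45 ± 1.07 here), Pax3 (-4.31) and Gpnmb (-4.19). In the PERK-deletion line Rpl34-ps1 (9.46), Rpl3-ps1 (8.84), Rps3a2 (8.71), Atp6v0c-ps2 (7.41), Hmga1b (6.87) and Dynap (6.82) were highest, and Col3a1 (-7.15, adjusted p = 2.78e-20), Fbln2 (-6.14), Col1a1 (-6.02, adjusted p = 2.64e-25; 1058 ± 235 TPM in WT, 15.1 ± 0.772 here), Bgn (-5.95), Ptgis (-5.81) and Hoxc11 (-5.55) lowest.

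No list passed between untreated lines with an estimated correlation. Smooth muscle markers were higher in 10 and lower in 1 of 11 in the GCN2-deletion line (Tagln 4.10, Actg2 3.81, Des -2.10, adjusted p = 2.49e-08, 0.0501 with an estimated correlation). They were higher in 7 and lower in 2 in the PERK-deletion line (Tagln 3.13, Myl9 2.70, adjusted p = 0.0479, 0.496 with an estimated correlation). Interferon genes were lower in 16 of 18 in the GCN2-deletion line (Oasl2 -3.03, Isg15 -2.49, adjusted p = 1.16e-07, 0.0653 with an estimated correlation) and synthesis genes in 13 of 15 (2 higher and 13 lower adjusted over the list alone, Aldh1l2 -1.82, Cth -1.71, adjusted p = 5.48e-06, 0.282 with an estimated correlation). Collagens were higher in 19 and lower in 3 of 26 in the GCN2-deletion line (21 higher and 3 lower adjusted over the list alone, Col6a3 3.18, Col3a1 -1.24, adjusted p = 1.16e-07, 0.282 with an estimated correlation), and higher in 7 and lower in 17 in the PERK-deletion line (adjusted p = 7.92e-07, 0.382 with an estimated correlation).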

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

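Tests chosen only after the result was seen were those on sterol genes and on the number of lines for starvation in the PERK-deletion line, the rescaling test, all tests with other splits of the libraries, and the version of these with means removed.

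Results here were picked because a stress effect differed between a deletion line and WT in a direct test. The 2-fold counts in the GCN2-deletion and PERK-deletion lines were 245 and 271 for starvation and 294 and 262 for thapsigargin. Genes named for passing one of these tests are not listed again. The kinases and the panel were named whether or not they passed.

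For starvation in the GCN2-deletion line minus WT, the log2 differences that passed were Trib3 -5.11, Chac1 -4.41, Sesn2 -3.32, Ddit3 -3.01, Ppp1r15a -2.55, Atf3 -1.97, Asns -1.42, Xbp1 -1.07, Dnajb9 -1.01, Atf4 -0.98, Psat1 -0.61, Hspa5 -0.51 and Eif2ak2 0.71. For starvation in the PERK-deletion line they were Trib3 -3.12, Atf3 -2.93, Chac1 -2.64, Ppp1r15a -2.58, Ddit3 -2.21, Sesn2 -2.18, Dnajb9 -1.02, Asns -0.98, Atf4 -0.93, Xbp1 -0.63, Psat1 -0.27 and Eif2ak3 0.55. For thapsigargin in the PERK-deletion line they were Ppp1r15a -2.84, Atf3 -2.79, Trib3 -2.76, Chac1 -2.22, Sesn2 -1.68, Ddit3 -1.68, Atf4 -0.77, Asns -0.67 and Dnajb9 -0.59. For thapsigargin in the GCN2-deletion line they were Chac1 1.30, Trib3 1.20, Sesn2 0.69, Atf3 0.67, Asns 0.60, Psat1 0.40, Atf4 0.21, Ppp1r15a -0.69, Ddit3 -0.29 and Hspa5 -0.29. Of these Atf4, Atf3, Ddit3 and Hspa5 depended on single libraries.

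The ATF4 program was little induced by starvation in the PERK-deletion line, although GCN2 and not PERK is the kinase that senses uncharged tRNA. The tables argue against starved libraries of this line being untreated ones, since 23 of 24 sterol genes fell. A change of medium alone stays open. The tables also argue against stress genes that were high before starvation: over the ATF4 and CHOP list, untreated PERK-deletion cells minus starved WT cells had a median log2 of -2.17 (quartiles -2.67 and -1.47), with 24 of 25 genes lower. Without starved replicate 1, which stood apart, Trib3 still differed from WT by -2.91 and Chac1 by -2.405. A need for PERK in this response, another difference of the line and a weaker starvation cannot be told apart. The labels hold 1 PERK-deletion line and 1 starved group of it. Its Eif2ak4 level did not differ from WT in the untreated groups.

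Thapsigargin responses in the GCN2-deletion line were higher than those in WT for most called genes, 86.3%. After rescaling the share was 54%, but rescaling centres the median change (0.132 before, -0.021 after), which fixes the share near balance, so scaling as a cause stays open. Genes of small RNAs and other noncoding classes do not account for it, since 87% of called protein-coding genes had higher responses. Nor does 1 library account for the share, at least 82.7% whichever was left out, though the count of higher responses, 1978, ran from 963 to 2737. The composition of these libraries shifted as well, which stays open as a cause: processed pseudogenes took 5.96 to 7.90% of TPM with thapsigargin against 3.65 to 3.91% with DMSO (3.48 to 4.12 and 3.48 to 3.99% in WT), and mitochondrial transcripts 4.27 to 5.78 against 6.39 to 7.29%. A change in total RNA per cell was not tested, and stays open too.

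Other splits of the same libraries gave this. In each comparison of 2 groups the 6 libraries make 10 splits, too few for a share under 0.05. The real count and the highest other were 428 and 1 for starvation and 370 and 37 for thapsigargin in WT, 195 and 2 and 580 and 3 in the GCN2-deletion line, and 114 and 3 and 85 and 2 in the PERK-deletion line. For DMSO they were 0 and 30 in WT, and 2 and 2 in each deletion line. For the untreated lines they were 1567 and 79, and 1655 and 61. The WT DMSO split with 30 genes points to a structure among the untreated and DMSO libraries of WT.

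For differences of effects 100 splits were drawn, which exchange libraries between arms (lines, or stresses in WT). The share of splits with as many genes, the real one included, was 11 of 100 for starvation in the GCN2-deletion (245 real, 2708 highest other) and PERK-deletion line (271, 2897). It was also 11 for thapsigargin in the GCN2-deletion (294, 3230) and PERK-deletion line (262, 3623). It was 11 for GCN2-dependent genes (178, 649), 10 for PERK-dependent genes (187, 529), 6 for PERK-selective genes (58, 89), 7 for starvation against thapsigargin in WT (317, 492) and 3 for GCN2-selective genes (29, 49). Splits that call several times the real count point to a structure of the samples: they carry the overall difference between lines into the effect. Such splits do not measure chance, so none of these shares, the 3 included, is taken to exclude it.

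With the mean difference between the arms removed, a version added after the first was seen, only the real split, 1 of 100, reached its count in each case. The highest other was 201 for starvation against thapsigargin in WT. In the GCN2-deletion and PERK-deletion lines the highest others were 203 and 87 for starvation and 132 and 60 for thapsigargin. They were 90 for GCN2-dependent, 5 for GCN2-selective, 78 for PERK-dependent and 6 for PERK-selective genes, the last against 59 real genes in this version. Added later, this version is not taken to exclude chance.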

How the results depend on the processing

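Tests with protein-coding genes only, without the 6 libraries of high microRNA share and with array weights gene by gene were chosen only after the data were seen; the last was added because the default weights did not converge (0.0107 to 14.4, against 0.183 to 4.17 gene by gene).

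Of 451 recomputed values of 20 counts, 386 lay within 1.5 times the reported count. Of 6070 recomputed values of named genes under other settings, 5716 kept their side of the threshold, 249 no longer passed, 101 passed newly and 4 reversed. With 1 library left out the numbers were 3594, 315, 15 and 0 of 3924. Direction was compared only where the reported or the recomputed value passed. Changes of sign among values that passed in neither are not counted. Of 597 list values 420 kept their call and 177 lost it, 156 of these with an estimated correlation. Reversed with the controls exchanged were Mir8111 for starvation in the GCN2-deletion line minus WT (-0.027) and Asns for starvation against thapsigargin in WT (-0.002). Hspa5 reversed for thapsigargin in the GCN2-deletion line minus WT with quantile normalization (0.28), and Fgf21 there with a pseudocount of 0.1 (0.34).

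Counts of 2-fold changes that moved further, by setting, were these; the cause was not tested except where fewer genes or libraries entered. With a pseudocount of 0.1, which widens changes of genes at low TPM by construction, they were 729 for starvation and 671 for thapsigargin in WT, 375 and 912 in the GCN2-deletion line, 220 for starvation in the PERK-deletion line, 462 and 395 for thapsigargin in the GCN2-deletion and PERK-deletion lines minus WT, 486 for starvation against thapsigargin in WT, and 2, 4 and 5 for DMSO in WT, the GCN2-deletion and the PERK-deletion line. With default array weights they were 567 for thapsigargin in WT, 473 for starvation in the GCN2-deletion line, 440 for starvation and 140 for thapsigargin in the PERK-deletion line, 717 and 427 for thapsigargin in the GCN2-deletion and PERK-deletion lines minus WT, 521 for starvation against thapsigargin, and 408 and 257 for DMSO in the GCN2-deletion and PERK-deletion lines. Gene by gene they were 344 for starvation in the GCN2-deletion line, 230 for starvation and 130 for thapsigargin in the PERK-deletion line, 372 for starvation in the GCN2-deletion line minus WT, 694 and 409 for thapsigargin in the GCN2-deletion and PERK-deletion lines minus WT, 51, 133 and 36 for DMSO in the 3 lines, and 52 GCN2-selective genes. With the controls exchanged they were 611 for thapsigargin in WT, 833 and 426 for thapsigargin in the GCN2-deletion and PERK-deletion lines minus WT, and 601 for starvation against thapsigargin.

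With median-of-ratios rescaling there were 54 GCN2-selective genes and 4 DMSO genes in WT, and with quantile normalization 46 and 4. With protein-coding genes only, fewer genes tested, there were 74 for starvation in the PERK-deletion line and 0 for DMSO in either deletion line. Without the 6 libraries there were 44 GCN2-selective genes, and 11 and 5 for DMSO in the GCN2-deletion and PERK-deletion lines. No filter gave 2 for DMSO in WT and 6 in the PERK-deletion line, the 5 TPM filter 0 in the GCN2-deletion and 1 in the PERK-deletion line, and the compared groups alone 3 in WT and 5 in the PERK-deletion line. Variances without trend and DMSO groups in place of untreated ones moved no count beyond 1.5 times.

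With each library left out in turn the ranges were 406 to 529 for starvation and 344 to 426 for thapsigargin in WT, 161 to 229 and 553 to 610 in the GCN2-deletion line, and 114 to 129 and 84 to 93 in the PERK-deletion line. For differences from WT they were 222 to 280 and 254 to 325 for starvation, and 164 to 488 and 247 to 303 for thapsigargin, in the GCN2-deletion and PERK-deletion lines; for starvation against thapsigargin 292 to 402. For DMSO they were 0 to 84, 3 to 6 and 3 to 8; for the untreated lines 1487 to 1709 and 1618 to 1712. Classes ran from 156 to 203 (GCN2-dependent), 23 to 36 (GCN2-selective), 175 to 201 (PERK-dependent) and 46 to 63 (PERK-selective). Libraries behind the 164 to 488 and the 84 are named above.

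Replicate numbers did not pair the libraries across groups. Deviations from the group mean correlated by 0.0017 on average between libraries of the same number (-0.179 to 0.352), 192 of 198 such pairs lay below 0.1, and 14 of 36 libraries correlated best with their own number. Replicate number as a block moved the WT DMSO count from 0 to 1 and ended 2 list calls. What depth limits could not be measured from TPM.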

Other observations

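No test here was chosen before its result was seen except the one on the sums of gene copies and their parents; the genes in the next paragraph were named after their values were seen.

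Some genes answered a stress in all 3 lines, or with starvation perhaps the change of medium. With starvation 454 genes rose and 432 fell in every line (13.6 and 21.7 for independent sets), 15 and 13 of them at least 2-fold in each (0.00719 and 0.00265 for independent sets). The 15 were Tnnt2, Rgs16, Ctgf, Tmcc3, Egr3, Has2, Hbegf, Ldlrad4, Ctsw, Errfi1, Areg, Wnt11, Tcim, Acsbg1 and Sema7a. The 13 included Insig1, Hmgcs1, Idi1, Sqle, Cyp51, Msmo1, Mvd and Fdft1 of sterol supply and the protease genes Adamts1 and Adamts5. With thapsigargin 23 rose and 5 fell at least 2-fold in every line (0.021 and 0.00221 for independent sets); the 5 were Retreg3, Scara3, Angptl2, Pbxip1 and Oaf.

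In the GCN2-deletion line, starvation lowered part of the program it raises in WT. Of the 240 genes that rose 2-fold in WT, 42 fell there (29.2 for independent sets), while 92 rose (28.2). Trib3, Chac1, Ddit3, Sesn2 and Herpud1 were among the 42; Herpud1 went from 36.6 ± 1.57 to 15.3 ± 0.746 TPM, and from 48.8 ± 1.13 to 194.9 ± 11.2 in WT. The lowering was not tested for its cause. The PERK-deletion line lay between: Trib3 did not pass there, and Ddit3 fell by 0.27.

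Processed copies of genes differed by over 5 log2 units between untreated lines in 13 cases, 9 distinct copies, such as Rpl34-ps1, at 0.0831 TPM in WT and 862.2 TPM in the GCN2-deletion line. A hypothesis is that reads are divided differently between copy and parent. In 92.3% of the cases (12 of 13) the sum of copy and parent moved by less than 1 log2 unit (at most 1.28), and in 12 the parent moved the other way. But with the parent at its WT level 0 of the copies was abundant enough to move the sum by 1 unit, so this test could not have come out otherwise, and shared reads and real expression of a copy cannot be told apart. A strain variant against the reference stays open too, since 0 labels name a strain. Values of these copies, and of Eno1b and Hmga1b, are therefore given in the report without a reading.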
